A study of Mus musculus with 23 samples.

How the data were processed

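The 23 arrays measured biotin-labelled cRNA made from total RNA of primary mouse aortic endothelial cells kept for 48 h in medium with 10% plasma of ApoE-KO (5 arrays), ApoE-Stab1-KO (6), ApoE-Stab2-KO (6) or wildtype mice (6). Per the submitters' processing notes, the deposited values were made with RMA, which corrects background, normalizes arrays by quantiles and summarizes the probes of a set; its version and the probe annotation are not given in the sources used here. The deposited values are on the log2 scale, as their range (2.52 to 13.9) shows, and 1 table of 25428 probe sets held all arrays. The sorted values of each array differed from those of ApoE-KO replicate 2 by at most 0.0019, as quantile normalization across all arrays leaves them. In ApoE-KO replicate 1, 4.21% of the values lay on a fixed binary grid of decimals, against 100% in each of the other arrays, so this array was stored with finer decimals. Because the arrays share 1 distribution of values, changes are relative to the other genes of an array, and a shift of all genes together would not be seen.

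Groups came from the sample labels. Each probe set was named from the annotation of the array platform, in which 24705 probe sets had 1 gene symbol, 0 had several and 723 had none. The 723 without a symbol were left out of the tests of named genes. Where 1 symbol stood on 2 probe sets, the brighter one was kept, which left 24704 genes. The mouse assembly GRCm38.p6 was used only for the class of each gene: 24672 genes had an entry, 19683 of them protein-coding and 4989 of other classes, and 32 had none. The build behind the array annotation is not given in the sources used here, so no coordinates are printed.

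Differences were tested with limma 3.58.1 in R 4.3.3 on the deposited log2 values, with lmFit and eBayes (no trend, not robust) and 1 mean per group over all 23 arrays, which share 1 estimate of the spread (19 residual and 4.19 prior degrees of freedom). The 6 pairwise comparisons and the moderated F-test over the 4 groups were each adjusted by Benjamini-Hochberg over 24704 genes, and genes with an adjusted p under 0.05 are called. There was no filter on dim genes. Adjusted p-values printed beside a gene are from this fit, and errors of differences are its standard errors. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

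In all, 30 gene lists with 618 distinct genes were fixed before the data were examined, as were the tests, the samples in each fit and the rule for named genes, and 582 of the list genes were measured. They cover cholesterol synthesis, fatty acid synthesis, cholesterol efflux with LXR targets, lipid uptake and oxidation, adhesion and NF-kB, interferon, flow-protective genes, coagulation, endothelial identity, angiogenesis and Notch, mesenchymal transition, TGF-beta targets, matrix, cell cycle, NRF2 targets, ER stress and amino acid response, heat shock, hypoxia and glycolysis, p53 targets, immediate early genes, scavenger receptors, circadian genes, glucocorticoid targets, complement and MHC, and markers of muscle, fibroblast, macrophage, lymphatic, blood and liver cells. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 30 lists of a comparison, and again with the correlation estimated from the data. A two-sided exact permutation test of the mean of each list per array was added after the data had been seen, as was Fisher's exact test of the share of calls outside protein-coding genes (adjusted over the 6 comparisons).

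The rule for named genes took, in the 4 comparisons among knockout plasmas and of ApoE-KO with wildtype, the 10 highest and 10 lowest called genes, leaving out predicted, Riken and small RNA names, and where fewer than 10 genes passed also the 5 smallest unadjusted p. To these it added Apoe, Stab1, Stab2, Tgfbi, Postn and Reln in every comparison, up to 4 members with the smallest p in each list described, and the 10 smallest p of the F-test. Gm16617, Gm13609 and Mir1896 entered through the F-test, and Gm16617 and Mir1896 also through the smallest unadjusted p for ApoE-Stab2-KO minus ApoE-KO, although the first part of the rule leaves out such names. Cyp26b1, Ereg, Dhrs9, Smad1, Mcam and Hlx were chosen after their values were seen.

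Alternatives were quantile normalization again, centring each array on its median, genes above the median level only, eBayes with trend and robust settings, array weights, the replicate number as a block, each probe set as its own feature, only the arrays of the groups compared, a fold of at least 1.5 in addition to the adjusted p, and each array left out in turn. For lists, the estimated correlation and fry were tried. Protein-coding genes only, and the permutation test of list means, were added after the data had been seen. Correlations between comparisons that share arrays were set beside 100 draws of simulated unchanged groups and beside 20 splits of the shared arrays.

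The fit was tested on simulated data with 200 changed genes among 24704. Of genes changed by 0.3 on the log2 scale it recovered 59.7% for ApoE-Stab1-KO minus ApoE-KO, 61.2% for ApoE-Stab2-KO minus ApoE-KO, 58.2% for ApoE-Stab2-KO minus ApoE-Stab1-KO and 67.2% for ApoE-KO minus wildtype. Of genes changed by 0.5 it recovered 94.0%, 92.5%, 92.5% and 92.5%. Against wildtype plasma, the shares at 0.3 were 46.3% for ApoE-Stab1-KO and 64.2% for ApoE-Stab2-KO. The simulated noise was independent between genes. The simulations gave 181, 181 and 169 calls in the 3 comparisons among knockout plasmas, where the data gave 1, 6 and 12. With fewer calls the adjustment requires a smaller unadjusted p, so these shares do not carry over to those comparisons and may overstate recovery there. False calls among all calls were 12 of 181, 13 of 181, 3 of 169 and 9 of 182 in the first 4 comparisons, and 16 of 175 and 4 of 172 for ApoE-Stab1-KO and ApoE-Stab2-KO minus wildtype, so in some single simulations the share was above the nominal 5%.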

Results

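Gene expression was measured in primary mouse aortic endothelial cells, the cells that line the inner wall of the aorta, after 48 h in medium whose serum had been replaced by 10% mouse plasma. The plasma came from mice lacking apolipoprotein E (ApoE-KO, n = 5 arrays), from mice lacking apolipoprotein E together with the scavenger receptor Stabilin-1 (ApoE-Stab1-KO, n = 6) or Stabilin-2 (ApoE-Stab2-KO, n = 6), or from wildtype mice (n = 6). Apolipoprotein E lets the liver take up lipoprotein remnants, and mice without it are known for high plasma cholesterol on Western diet. Stabilin-1 and Stabilin-2 are receptors of sinusoidal endothelium that clear ligands such as TGFBI, periostin and reelin from blood. The knockout donors had received Western diet for 8 weeks, and the labels give no diet for the wildtype donors, so genotype and diet could not be separated in any comparison with wildtype plasma. The genotypes are those of the plasma donors and not of the cells. The 23 arrays gave log2 values for 24704 genes, which ranged from 2.52 to 13.9 with a median of 4.33. Pairs of arrays correlated across genes at r = 0.992 to 0.997, and no 2 arrays held identical values. The number of arrays limits the precision, and the median standard error of a log2 difference between 2 groups was 0.07 in each comparison. The labels do not say whether replicates came from separate cultures or plasma donors, so the p-values measure the spread between these samples, which may be technical.

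Across the 4 plasma groups, 135 genes differed (limma moderated F-test, Benjamini-Hochberg adjusted p under 0.05), and 2952 had an unadjusted p under 0.05. The smallest adjusted p-values belonged to Msmo1 (5.05e-05), Gm16617, which is not protein-coding, Cyp51, Lss and Sema3e (6.33e-05 each), Sema3c and Sprr1a (7.94e-05 each) and Hmgcs1 (0.000107), of which Msmo1, Cyp51, Lss and Hmgcs1 encode enzymes of cholesterol synthesis. Without wildtype replicate 4, 87 genes passed.

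The comparison of ApoE-KO with wildtype plasma asks how aortic endothelial cells differ after exposure to plasma of ApoE-deficient mice on Western diet. With ApoE-KO plasma, 84 genes were higher and 47 lower, out of 2602 at an unadjusted p under 0.05 where 1235 would be expected by chance. Genes of cholesterol synthesis, a list of the pathway's enzymes and some sterol-responsive regulators, rose as a group. Of the 20 measured members of that list, 12 rose, 0 fell and 8 did not pass, 17 rose when adjusted over the list alone, and 5 further members were not analysed here. The log2 difference was 0.69 ± 0.06 (SE) for Msmo1, a methylsterol oxidase (adjusted p = 2.85e-06), 0.71 ± 0.07 for Lss, the lanosterol synthase (8.99e-06), 0.68 ± 0.07 for Cyp51, the lanosterol demethylase (8.99e-06), and 0.53 ± 0.06 for Hmgcs1, which makes the HMG-CoA that feeds the pathway (1.22e-05). Squalene epoxidase Sqle rose by 0.45 ± 0.05 (8.27e-05), Nsdhl by 0.56 ± 0.07 (7.37e-05), Hsd17b7 by 0.57 ± 0.10 (0.00654) and Dhcr7, the enzyme of the last step to cholesterol, by 0.39 ± 0.06 (0.000948). Averaged over the list, the level was 8.26 ± 0.06 (SD, n = 5) with ApoE-KO plasma and 7.87 ± 0.06 (SD, n = 6) with wildtype plasma. The arrays did not overlap (8.17 to 8.35 against 7.77 to 7.93), and the difference of 0.39 ± 0.03 (SE) corresponded to 1.31-fold. The list was called by camera (adjusted p = 6.92e-40, and adjusted p = 6.32e-06 with an estimated correlation) and by a two-sided exact permutation test of the list means (adjusted p = 0.0162).

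**Figure D1:**
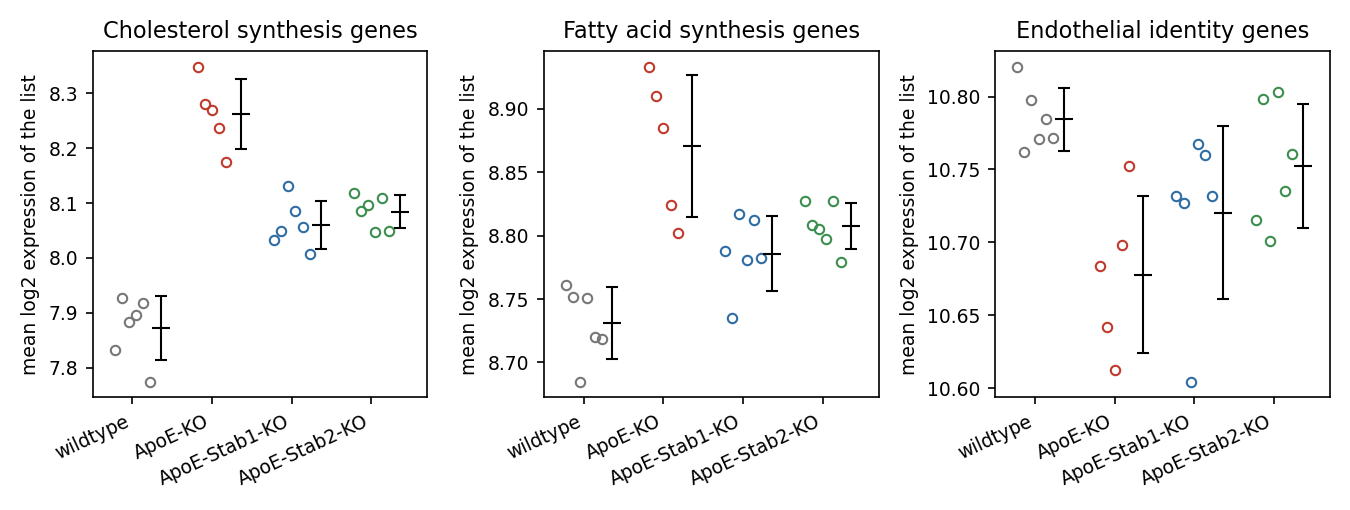
Mean log2 level per array (y axis) of the cholesterol synthesis, fatty acid synthesis and endothelial identity lists in the 4 plasma groups (x axis); each point is 1 array, and the symbol to the right of the points gives the group mean ± SD. For cholesterol synthesis the ApoE-KO arrays lie at 8.17 to 8.35, the ApoE-Stab1-KO arrays at 8.01 to 8.13, the ApoE-Stab2-KO arrays at 8.05 to 8.12 and the wildtype arrays at 7.77 to 7.93.

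Lipid genes outside cholesterol synthesis also differed between ApoE-KO and wildtype plasma. In the list of fatty acid synthesis, 3 of 15 genes rose and 12 did not pass, and 8 rose when adjusted over the list alone (median log2 difference 0.10, camera adjusted p = 5.79e-08, and adjusted p = 0.00376 with an estimated correlation). The 3 genes were the elongase Elovl6 (0.42 ± 0.07, adjusted p = 0.00148) and the desaturases Fads2 (0.37 ± 0.06, 0.00221) and Scd1 (0.43 ± 0.08, 0.0111). Among 12 genes of cholesterol efflux and LXR targets, the cholesterol exporter Abca1 fell (-0.44 ± 0.08, 0.00654) and 11 did not pass, and the list was not called by camera (adjusted p = 0.366, 1 higher and 2 lower when adjusted over the list alone). Among 21 genes of lipid uptake and oxidation, the fatty acid receptor Cd36 rose (0.32 ± 0.07, 0.0487), 2 were higher and 1 lower when adjusted over the list alone, and the list was not called (0.095). Among 21 scavenger receptor genes, Cd36 and the lipoprotein receptor Lrp8 (0.24 ± 0.04, 0.00654) rose, 19 did not pass, 3 were higher and 3 lower when adjusted over the list alone, and the list was not called by camera (0.0737). Stab2 in these cells differed by -0.29 ± 0.07 (0.0547) and Stab1 by -0.19 ± 0.05 (0.114), neither past the threshold, and Apoe by -0.02 (0.974). The Stabilin ligand genes Tgfbi (-0.02), Postn (0.03) and Reln (0.10) did not pass either, with Postn and Reln below the median level of the arrays.

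Endothelial and angiogenic genes moved with ApoE-KO plasma as well. Of 25 endothelial identity genes, 2 fell and 23 did not pass, and 6 fell when adjusted over the list alone (median -0.08, camera adjusted p = 1.63e-09, and adjusted p = 0.0377 with an estimated correlation). They were Egfl7, a secreted endothelial protein (-0.27 ± 0.04, 0.00136), and Cldn5, a claudin of endothelial tight junctions (-0.27 ± 0.06, 0.0459). In the angiogenesis and Notch list of 24 genes, the growth factor Vegfa rose (0.26 ± 0.05, 0.0251), the Notch ligand Dll4 fell (-0.46 ± 0.07, 0.00257) and so did Pdgfb (-0.28 ± 0.05, 0.00412), while 21 did not pass and 1 rose and 4 fell when adjusted over the list alone. This list was lower by camera (adjusted p = 0.00966), but not with an estimated correlation (adjusted p = 0.0892 with an estimated correlation) or without wildtype replicate 1 (camera adjusted p = 0.0524). The hypoxia and glycolysis list was higher (25 genes, median 0.12, camera adjusted p = 7.83e-05, and adjusted p = 0.0188 with an estimated correlation), with Vegfa as its 1 gene past the threshold and 4 higher when adjusted over the list alone. The list of ER stress and amino acid response was higher by camera (25 genes, median 0.08, adjusted p = 4.82e-05, but adjusted p = 0.0892 with an estimated correlation). Its 3 genes past the threshold were the transcription factor Atf5 (0.42 ± 0.09, 0.0255), the serine synthesis enzyme Psat1 (0.29 ± 0.06, 0.0461) and the folate enzyme Mthfd2 (0.46 ± 0.11, 0.0482), and 6 rose when adjusted over the list alone. The cell cycle list of 39 genes was lower by camera (median -0.06, adjusted p = 0.00743, but adjusted p = 0.431 with an estimated correlation), with 1 gene higher and 0 lower, over all genes as when adjusted over the list alone, and this call ended without ApoE-KO replicate 2 (0.0812) or replicate 4 (0.0911). Among lists that camera did not call, Thbs1, an inhibitor of angiogenesis (0.57 ± 0.10, 0.0094), and Ccn2, a matrix-associated growth factor (0.51 ± 0.11, 0.034), were the 2 of 24 TGF-beta targets that rose, with 3 higher when adjusted over the list alone (camera adjusted p = 0.183). The metallothioneins Mt2 (0.46 ± 0.09, 0.0144) and Mt1 (0.25 ± 0.06, 0.0407) were the 2 of 15 glucocorticoid targets that rose, with 4 higher when adjusted over the list alone (camera adjusted p = 0.0501). The exact permutation of list means, which does not set a list against the other genes, called 6 lists that camera did not: scavenger receptors (0.026), TGF-beta targets (0.0371), cholesterol efflux with LXR targets, circadian genes, complement and MHC (0.0472 each) and p53 targets (0.0487). It did not call the cell cycle list (0.186).

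The gene that rose most with ApoE-KO plasma among those called was Sprr1a, a small proline-rich protein first known from keratinizing epithelia (1.16 ± 0.14, 2.24-fold, adjusted p = 7.37e-05). Also higher were the genes of the mitochondrial folate enzyme Aldh1l2 (0.82 ± 0.15, 0.01), the secreted guidance factor Sema3c (0.74 ± 0.08, 3.22e-05) and the aldehyde dehydrogenase Aldh1a7 (0.69 ± 0.13, 0.00985). The immune receptor gene Havcr2 (0.58 ± 0.07, 7.37e-05) and a further semaphorin, Sema3e (0.50 ± 0.06, 9.75e-05), rose too. Outside protein-coding genes, Gm13609 (-0.82 ± 0.14, 0.00638) and Gm16617 (-0.68 ± 0.10, 0.000639) fell. The protein-coding genes that fell included Ly6f (-0.59 ± 0.12, 0.0241), Nwd1 (-0.57 ± 0.08, 0.000802), the butyrophilin-like gene Btnl9 (-0.50 ± 0.10, 0.0255), Cstad (-0.47 ± 0.10, 0.0355) and the gluconeogenic enzyme gene Fbp1 (-0.41 ± 0.07, 0.00815). Ttyh1 (0.0111), the small GTPase gene Gem (0.0101) and the GTPase gene Gimap6 (0.00985) each fell by 0.38. Only 12 of the 131 genes differed by 1.5-fold or more. The count fell to 55 without ApoE-KO replicate 2, 69 without ApoE-KO replicate 3, and 78, 87, 85 and 81 without wildtype replicates 1, 4, 5 and 6. Of the 50 called genes followed through these fits, 34 passed in every one, among them the 8 cholesterol synthesis genes named here, and the 16 that did not were Aldh1l2, Ly6f, Btnl9, Cstad, Cldn5, Vegfa, Atf5, Psat1, Mthfd2, Mt1, Mt2, Ccn2, Cd36, Cyp26b1, Smad1 and Hlx. Each of the 11 arrays, left out alone, ended at least 1 of these calls, with adjusted p-values of 0.0508 to 0.17.

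The comparison of ApoE-Stab1-KO with ApoE-KO plasma asks what the additional loss of Stabilin-1 in the donor changes in the response of the cells. With ApoE-Stab1-KO plasma, Dhcr7 was the 1 gene past the threshold, and it fell (-0.38 ± 0.06, 0.768-fold, limma with Benjamini-Hochberg adjusted p = 0.0259). The cholesterol synthesis list fell as a group. Of its 20 measured members 1 fell and 19 did not pass, 14 fell when adjusted over the list alone, 19 had a negative difference, and the median was -0.23. The list mean was 8.06 ± 0.04 (SD, n = 6) with ApoE-Stab1-KO plasma, and the difference from ApoE-KO plasma was -0.20 (95% interval -0.26 to -0.14). The list was called by camera (adjusted p = 5.49e-22, and adjusted p = 0.000386 with an estimated correlation). In the two-sided exact permutation test of list means its p was 0.00216, the smallest that the 462 splits of the 11 arrays allow, and its adjusted p of 0.0649 missed the threshold. Members that did not pass over all genes were Hmgcs1 (-0.31 ± 0.06, 0.141), Msmo1 (-0.33 ± 0.06, 0.16) and Cyp51 (-0.31, 0.425). The remaining genes with the smallest unadjusted p were Ptprcap (-0.38 ± 0.07, 0.141), which lay below the median level of the arrays, and the magnesium transporter gene Nipal1 (-0.37 ± 0.07, 0.16). Abca1 (0.26, 0.737), Abcg1 (0.23, 0.729) and the chemokine gene Ccl2 (-0.39, 0.56) did not pass. The differences of Apoe (0.02), Stab1 (0.09), Stab2 (-0.10), Tgfbi (-0.06), Postn (0.10) and Reln (-0.07) did not pass.

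Further lists shifted with ApoE-Stab1-KO plasma by less than 0.1 at the median, each with 0 genes past the threshold, and none of these calls held with an estimated correlation. Fatty acid synthesis was lower (median -0.08, camera adjusted p = 0.000253, but adjusted p = 0.0635 with an estimated correlation), and 5 of 15 genes fell when adjusted over the list alone. Interferon-stimulated genes were higher (median 0.08, 7.56e-05, but adjusted p = 0.317 with an estimated correlation), and 2 of 28 rose when adjusted over the list alone, one of them being the antiviral gene Rsad2 (0.37 ± 0.10, 0.648 over all genes). The cell cycle list (median 0.04, 0.00113, but adjusted p = 0.455 with an estimated correlation) and the endothelial identity list (median 0.04, 0.0241, but adjusted p = 0.552 with an estimated correlation) were higher by camera. So were p53 targets (median 0.05, 0.0241, but adjusted p = 0.221 with an estimated correlation) and complement and MHC genes (median 0.04, 0.0241, but adjusted p = 0.0906 with an estimated correlation). Immediate early genes (median -0.08, 0.00164, but adjusted p = 0.221 with an estimated correlation) and NRF2 targets (median -0.05, 0.0241, but adjusted p = 0.317 with an estimated correlation) were lower. The endothelial identity call ended without ApoE-KO replicate 2 (0.103) or 3 (0.403), or without ApoE-Stab1-KO replicate 2 (0.0695), 4 (0.157), 5 (0.114) or 6 (0.0668). The NRF2 call ended without ApoE-KO replicate 2 (0.103) or 3 (0.151) or ApoE-Stab1-KO replicate 1 (0.126), 4 (0.0622) or 6 (0.0577). The complement and MHC call ended without ApoE-KO replicate 2 (0.0557) or 3 (0.151) or ApoE-Stab1-KO replicate 1 (0.088) or 6 (0.0656), and the p53 call without ApoE-KO replicate 3 (0.151) or ApoE-Stab1-KO replicate 1 (0.22) or 6 (0.0502) or among genes above the median level (0.0576). The cell cycle call ended without ApoE-Stab1-KO replicate 3 (0.121). The number of lists called was 9 with all arrays and 5 without ApoE-KO replicate 3 or ApoE-Stab1-KO replicate 6. At the level of genes, the adjusted p of Dhcr7 was 0.0939, 0.191 and 0.0903 without ApoE-KO replicates 1, 2 and 4, and 0.105 and 0.0935 without ApoE-Stab1-KO replicates 1 and 5. No gene passed without ApoE-KO replicate 2 or 4 or ApoE-Stab1-KO replicate 1 or 5, where limma with all arrays had 1377 genes at an unadjusted p under 0.05, and 2 genes passed without ApoE-Stab1-KO replicate 2, 3 or 6.

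The comparison of ApoE-Stab2-KO with ApoE-KO plasma asks the same of the loss of Stabilin-2. With ApoE-Stab2-KO plasma, 3 genes rose and 3 fell, and 2065 had an unadjusted p under 0.05 where 1235 would be expected by chance. The cholesterol synthesis list fell here too. Of 20 measured members 1 fell and 19 did not pass, 11 fell when adjusted over the list alone, and the median was -0.22. The list mean was 8.08 ± 0.03 (SD, n = 6), a difference from ApoE-KO plasma of -0.18 (95% interval -0.24 to -0.12). The list was called by camera (adjusted p = 5.06e-15, and adjusted p = 0.00362 with an estimated correlation), while the two-sided exact permutation test gave p = 0.00216, the smallest it allows, and an adjusted p of 0.0649. Its member past the threshold was Hmgcs1 (-0.34 ± 0.06, adjusted p = 0.026). Msmo1 (-0.31, 0.142), Lss (-0.35, 0.142) and Sqle (-0.23, 0.209) did not pass. Havcr2 fell (-0.39 ± 0.07, 0.042), and so did the water channel gene Aqp4 (-0.24 ± 0.04, 0.026). The genes that rose were the olfactory receptor gene Olfr372 (0.34 ± 0.06, 0.026) and, outside protein-coding genes, Gm16617 (0.58 ± 0.10, 0.026) and the microRNA gene Mir1896 (0.94 ± 0.16, 0.026). Aqp4, Olfr372 and Gm16617 lay below the median level of the arrays. The differences of Apoe (-0.11), Stab1 (0.10), Stab2 (-0.11), Tgfbi (0.04), Postn (0.05) and Reln (-0.06) did not pass.

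**Figure D2:**
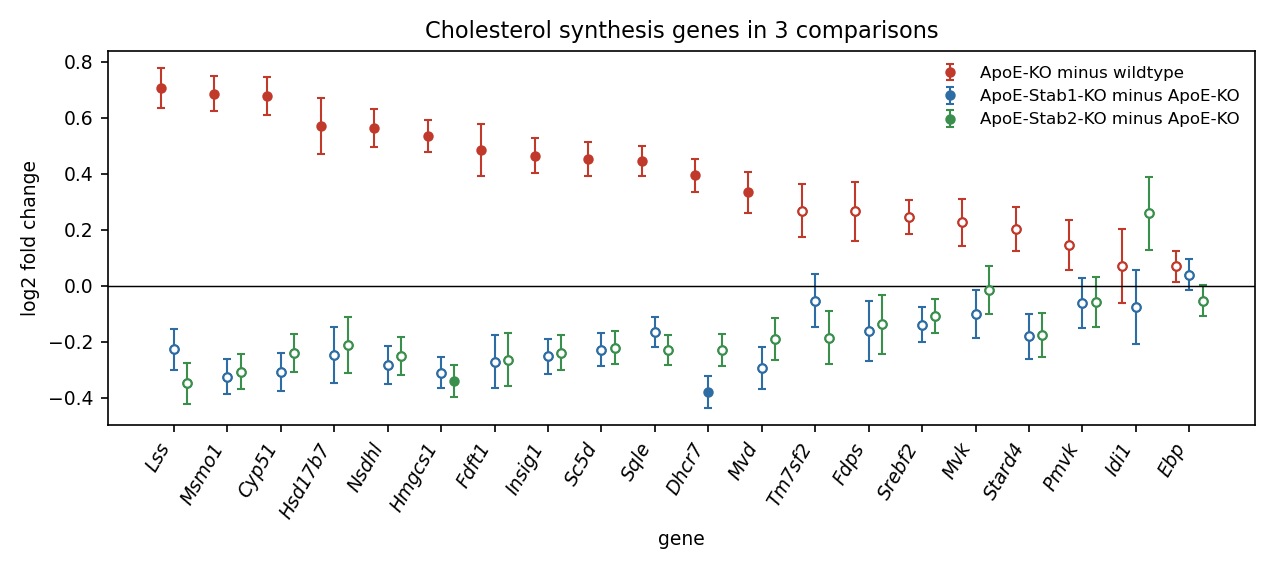
Log2 difference ± SE (y axis) of the 20 measured cholesterol synthesis genes (x axis). The comparisons are ApoE-KO minus wildtype plasma and each double knockout minus ApoE-KO plasma. Filled points passed an adjusted p of 0.05 over all genes and open points did not. The 20 differences are positive for ApoE-KO minus wildtype plasma, 12 of them past the threshold, and 19 of 20 are negative for each double knockout minus ApoE-KO plasma, 1 of them past the threshold in each.

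Endothelial identity genes were higher with ApoE-Stab2-KO than with ApoE-KO plasma by camera (median 0.04, adjusted p = 0.000929, but adjusted p = 0.484 with an estimated correlation), with 0 of 25 past the threshold over all genes and 4 higher when adjusted over the list alone. Cldn5 (0.27, 0.156) and the von Willebrand factor gene Vwf (0.49 ± 0.13, 0.255) had the smallest p in it, and neither passed. Fatty acid synthesis was lower (median -0.06, camera adjusted p = 0.024, but adjusted p = 0.455 with an estimated correlation), and 0 of 15 genes passed over all genes or adjusted over the list alone. This call ended without ApoE-KO replicate 1 (0.151) or 2 (0.103) or ApoE-Stab2-KO replicate 6 (0.0684). The cell cycle list was higher (median 0.04, 0.0298, but adjusted p = 0.548 with an estimated correlation), a call that ended without ApoE-KO replicate 1 (0.151), 2 (0.326) or 4 (0.234) or ApoE-Stab2-KO replicate 1 (0.193), 3 (0.173) or 6 (0.0669), or among genes above the median level (0.0612). Of the 4 lists called, 2 were called without ApoE-KO replicate 1 or 2 or ApoE-Stab2-KO replicate 6. Of single genes, 0 passed without ApoE-KO replicate 1, 2 or 3 or ApoE-Stab2-KO replicate 1, 2, 3, 5 or 6, 1 without ApoE-KO replicate 4 or ApoE-Stab2-KO replicate 4, and 12 without ApoE-KO replicate 5. In these fits the lost genes, Hmgcs1, Havcr2 and Aqp4 among them, had adjusted p-values of 0.0592 to 0.185.

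The direct comparison of ApoE-Stab2-KO with ApoE-Stab1-KO plasma asks whether the 2 Stabilins differ. It gave 9 higher and 3 lower genes (2712 at an unadjusted p under 0.05), of which 9 are not protein-coding genes in the reference annotation. Mir1896 (1.25 ± 0.15, adjusted p = 0.000694), Gm13609 (0.91 ± 0.14, 0.00487), Gm16617 (0.68 ± 0.09, 0.00192) and the ribosomal pseudogene Rpl36-ps3 (0.56 ± 0.10, 0.0168) were higher with ApoE-Stab2-KO plasma. The mean level of each was also lower with ApoE-KO than with wildtype plasma. For Gm16617 it was 3.86 with ApoE-KO and 3.76 with ApoE-Stab1-KO, against 4.44 with ApoE-Stab2-KO and 4.54 with wildtype plasma. These differences therefore cannot be assigned to the Stabilins, and a handling set of arrays could not be separated from them. Gm16617 lay below the median level of the arrays. The 3 protein-coding genes were Ecsit, a signalling adaptor also needed for mitochondrial complex I assembly (0.53 ± 0.08, 0.00554), Aph1b, a gamma-secretase subunit (-0.31 ± 0.05, 0.012), and Cgn, the tight junction protein cingulin (-0.52 ± 0.09, 0.0269). The share of calls outside protein-coding genes was 75% here against 20.3% of all genes tested, counting the 32 genes without a reference entry as outside (two-sided Fisher's exact test, adjusted p = 0.000262). This test treats genes as independent, which genes measured on the same arrays are not, so its p does not measure the spread between arrays. Without ApoE-Stab1-KO replicate 1, 14 of 37 calls were outside protein-coding genes, a lower share. The same test with all arrays went the other way for ApoE-KO minus wildtype (9.92% of 131 calls, adjusted p = 0.00426) and ApoE-Stab2-KO minus wildtype plasma (0% of 44 calls, adjusted p = 0.000262), and did not pass in the other 3 comparisons. The cholesterol synthesis list did not differ beyond the spread: the difference of list means was 0.02 (95% interval -0.04 to 0.08), 0 of 20 genes passed over all genes or adjusted over the list alone, and the camera adjusted p was 0.699. Dhcr7 (0.15, 0.31), Idi1 (0.34, 0.318) and Lss (-0.12, 0.536) did not pass. Immediate early genes were higher by camera (median 0.06, adjusted p = 0.0218, but adjusted p = 0.762 with an estimated correlation), with 0 of 24 past the threshold or adjusted over the list alone, and the call ended without ApoE-Stab1-KO replicate 2 (0.0797) or 3 (0.105) or ApoE-Stab2-KO replicate 2 (0.0732), 3 (0.079), 4 (0.0751) or 5 (0.0907), or among genes above the median level (0.0523). Rsad2 (-0.51 ± 0.10, 0.0522), Cldn5 (0.26, 0.0813) and Id1, a target of BMP signalling (0.38, 0.0681), did not pass. In the interferon list 1 gene was higher and 4 lower when adjusted over the list alone, and the list was not called (camera adjusted p = 0.168). The differences of Apoe (-0.12), Stab1 (0.00), Stab2 (-0.02), Tgfbi (0.10), Postn (-0.05) and Reln (0.01) did not pass. Without ApoE-Stab1-KO replicate 1 or 4 or ApoE-Stab2-KO replicate 6, 37, 32 and 19 genes passed. With only the 2 groups fitted, the calls of Ecsit (0.0963), Aph1b (0.135), Cgn (0.123) and Rpl36-ps3 (0.0641) ended. The call of Cgn also ended without ApoE-Stab2-KO replicate 2 (0.0565), 3 (0.0907), 4 (0.0686) or 5 (0.0657).

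Each double knockout plasma was also compared with wildtype plasma, to set its difference beside the one seen with ApoE-KO plasma. With ApoE-Stab1-KO plasma, 43 genes were higher and 47 lower than with wildtype plasma (2791 at an unadjusted p under 0.05). Cholesterol synthesis was higher: 4 of 20 genes rose and 16 did not pass, 11 rose when adjusted over the list alone, and the difference of list means, 0.19 ± 0.03 (SE), was 48.3% of that between ApoE-KO and wildtype plasma (camera adjusted p = 2.32e-13, and adjusted p = 0.00673 with an estimated correlation). Lss (0.48 ± 0.07, adjusted p = 0.00131), Cyp51 (0.37, 0.00898), Msmo1 (0.36 ± 0.06, 0.00528) and Sqle (0.28, 0.013) rose, and Hmgcs1 (0.22, 0.0716) and Dhcr7 (0.01, 0.959) did not pass. Dll4 (-0.56 ± 0.07, 0.000421) and Pdgfb (-0.33, 0.000692) fell and Vegfa rose (0.25, 0.0264) in an angiogenesis and Notch list that was lower (1 higher and 4 lower when adjusted over the list alone, camera adjusted p = 0.002, and adjusted p = 0.0498 with an estimated correlation). Of the scavenger receptors, Cd36 (0.40, 0.00779) and the collectin gene Colec12 (0.35, 0.0122) rose and Stab2 fell (-0.39, 0.00665), and the list was higher (4 higher and 1 lower when adjusted over the list alone, camera adjusted p = 0.0194, and adjusted p = 0.0498 with an estimated correlation), a call that ended among genes above the median level (0.135). Hypoxia and glycolysis genes were higher (median 0.11, 0.000124, and adjusted p = 0.0276 with an estimated correlation, 4 higher when adjusted over the list alone). Endothelial identity was lower with Egfl7 (-0.21, 0.0122) as its 1 gene past the threshold and 5 lower when adjusted over the list alone (0.000115, but adjusted p = 0.174 with an estimated correlation). The ER stress list was higher with Atf5 (0.42, 0.0185) and 4 higher when adjusted over the list alone (0.000397, but adjusted p = 0.173 with an estimated correlation).

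Fatty acid synthesis was higher with ApoE-Stab1-KO than with wildtype plasma, with 0 of 15 genes past the threshold and 4 higher when adjusted over the list alone (camera adjusted p = 0.0164, but adjusted p = 0.174 with an estimated correlation). Lipid uptake was higher, with Cd36 up, Gpihbp1, the endothelial anchor of lipoprotein lipase, down (-0.36, 0.0273), and 4 higher and 1 lower when adjusted over the list alone (0.0146, but adjusted p = 0.188 with an estimated correlation). The first of these calls ended without wildtype replicate 3 (0.0513) and the other without wildtype replicate 1 (0.132) or with the permutation test (0.0866). The transcription factor genes Nr4a1 (-0.35, 0.013), Fosl2 (-0.25, 0.0121) and Myc (-0.28, 0.0452) fell among 24 immediate early genes, 2 were higher and 6 lower when adjusted over the list alone, and that list was not called (0.0622). Mmp3, a matrix metalloproteinase gene (0.58 ± 0.10, 0.00773), was the 1 gene of the matrix list to rise, and F2r, a thrombin receptor gene (0.21, 0.049), the 1 gene of the coagulation list. Outside protein-coding genes, Gm13609 (-1.04 ± 0.14, 0.000599), Mir1896 (-0.83 ± 0.15, 0.0122) and Gm16617 (-0.77 ± 0.09, 0.000274) fell. The differences of Apoe (0.00), Stab1 (-0.10), Tgfbi (-0.09), Postn (0.13) and Reln (0.03) from wildtype plasma did not pass. The count of 90 genes fell to 57 without ApoE-Stab1-KO replicate 3, 54 without wildtype replicate 1 and 57 without wildtype replicate 4. Of 37 called genes followed through these fits, 26 passed in every one, and the 11 that did not were Havcr2, Nwd1, Rpl36-ps3, Aph1b, Vegfa, Atf5, Cyp1b1, Myc, Gpihbp1, F2r and Hlx, with adjusted p-values of 0.0501 to 0.108 where they failed. Each of the 12 arrays ended at least 1 of these calls.

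With ApoE-Stab2-KO plasma, 28 genes were higher and 16 lower than with wildtype plasma (2097 at an unadjusted p under 0.05). Cholesterol synthesis was higher: 4 of 20 genes rose and 16 did not pass, 14 rose when adjusted over the list alone, and the difference of list means, 0.21 ± 0.03 (SE), was 54.4% of that between ApoE-KO and wildtype plasma (camera adjusted p = 1.41e-19, and adjusted p = 0.00079 with an estimated correlation). Cyp51 (0.44 ± 0.07, adjusted p = 0.00244), Msmo1 (0.38, 0.00471), Lss (0.36, 0.0242) and Nsdhl (0.31, 0.041) rose, and Abca1 (-0.30, 0.137) did not pass. Lipid uptake was higher (0.000111, and adjusted p = 0.0455 with an estimated correlation), with the lipase inhibitor gene Angptl4 (0.34 ± 0.06, 0.00546) and Cd36 (0.36, 0.0244) up, and 6 higher and 1 lower when adjusted over the list alone. The angiogenesis and Notch list was lower (0.00215, and adjusted p = 0.0455 with an estimated correlation), with Dll4 (-0.40, 0.0119) and Pdgfb (-0.31, 0.00222) down, Vegfa (0.35 ± 0.05, 0.00222) up, and 1 higher and 4 lower when adjusted over the list alone. The ER stress list was higher (1.05e-05, and adjusted p = 0.0455 with an estimated correlation), with Psat1 (0.34, 0.0137) up and 4 higher when adjusted over the list alone. Fatty acid synthesis (0.000305, and adjusted p = 0.0455 with an estimated correlation) and TGF-beta targets (0.00131, and adjusted p = 0.0176 with an estimated correlation) were higher with 0 genes past the threshold over all genes, and with 3 and 5 higher when adjusted over the list alone. Hypoxia and glycolysis was higher (0.0048, but adjusted p = 0.0696 with an estimated correlation), with Vegfa and the glycolytic regulator gene Pfkfb3 (0.30, 0.0244) as the 2 genes that passed over all genes and adjusted over the list alone. Endothelial identity was lower (0.0048, but adjusted p = 0.302 with an estimated correlation and 0.229 with the permutation test; 1 higher and 3 lower when adjusted over the list alone), and glucocorticoid targets were higher (0.000305, but adjusted p = 0.0782 with an estimated correlation; 4 higher when adjusted over the list alone), both with 0 genes past the threshold over all genes.

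Stab2 also fell with ApoE-Stab2-KO relative to wildtype plasma (-0.40, 0.00546), and the differences of Apoe (-0.12), Stab1 (-0.09), Tgfbi (0.02), Postn (0.08) and Reln (0.04) did not pass. The count of 44 genes fell to 20 without ApoE-Stab2-KO replicate 3 and 29 without ApoE-Stab2-KO replicate 6. Of 27 called genes followed through these fits, 15 passed in every one, and the 12 that did not were Lss, Dll4, Fbp1, Gem, Nipal1, Psat1, Cd36, Nsdhl, Pfkfb3, Ereg, Dhrs9 and Smad1, with adjusted p-values of 0.0505 to 0.137 where they failed. Each of the 12 arrays ended at least 1 of these calls.

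Across the 24704 genes, which are not independent replicates, the differences of the 2 double knockouts from ApoE-KO plasma correlated at r = 0.38 (covariance 0.003478). Both share the ApoE-KO arrays, and simulated unchanged groups gave a mean r of 0.53 (range 0.34 to 0.71 over 100 draws) and a covariance of 0.004365. With the ApoE-KO arrays split between the comparisons, the mean r was -0.02 (range -0.18 to 0.08 over 20 splits), so no shared direction beyond the shared arrays was detectable across all genes. The differences of ApoE-Stab1-KO from ApoE-KO plasma correlated with those of ApoE-KO from wildtype plasma at r = -0.42 (covariance -0.004146, simulated -0.004384), and with split arrays at -0.03. For ApoE-Stab2-KO the correlation was r = -0.57 (covariance -0.006018, simulated -0.00428). Both values lay within the simulated ranges over 100 draws (r -0.68 to -0.25, covariance -0.006569 to -0.001952). Without a split, this correlation therefore shows nothing beyond the shared arrays. With split arrays the mean r was -0.16 (range -0.24 to -0.03 over 20 splits). In simulated unchanged groups the mean over splits ranged from -0.14 to 0.25 over 100 draws, so the observed mean lay slightly below that range. Between the calls of the 2 double knockouts against ApoE-KO plasma, 0 genes were shared, with 1 and 6 genes called.

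None of the 6 lists of other cell types was called in any comparison. For muscle cell, fibroblast, macrophage, lymphatic, blood cell and liver markers the lowest camera adjusted p over the 6 comparisons was 0.368, 0.127, 0.313, 0.386, 0.251 and 0.207, and 0 of their genes passed over all genes in any comparison. The lists of NF-kB and adhesion genes (0.212), flow-protective genes (0.198), coagulation (0.287), mesenchymal transition (0.416), matrix (0.744), heat shock (0.0908), circadian genes (0.148) and cholesterol efflux with LXR targets (0.0815) were likewise not called by camera in any of the 6 comparisons. The exact permutation of list means called coagulation for ApoE-Stab2-KO minus wildtype (0.0186), and circadian genes and LXR targets for ApoE-KO minus wildtype plasma. Of these, flow-protective genes held Cyp1b1, a cytochrome P450 gene that rose against wildtype plasma with ApoE-KO (0.45 ± 0.09, 0.0133), ApoE-Stab1-KO (0.39, 0.0365) and ApoE-Stab2-KO plasma (0.46, 0.0119).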

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

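Of the tests in this part, the search for single arrays far from their group followed a fixed rule, and both tests on ApoE-Stab1-KO replicate 1 were chosen only after the result was seen. A single array stood far from the others of its group, by Dixon's criterion, in 27 of 452 tests of named genes, lists and array measures. Chance gives about 1 in 20, or 23, so the number of such tests is near that of chance. Some named genes are also list members, so the tests are not independent. The total does not tell whether a given array stands apart.

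ApoE-Stab1-KO replicate 3 lay below its group in 4 genes and 2 lists. Its log2 level was 10.57 for Cldn5 (others 10.87 to 11.02), 7.83 for Vwf (8.34 to 8.62), 6.05 for Ly6f (6.38 to 6.45) and 10.99 for Rpl36-ps3 (11.41 to 11.56). Its list mean was 10.60 for endothelial identity (10.73 to 10.77) and 8.77 for coagulation (8.83 to 8.85). Wildtype replicate 1 was low in Aldh1l2 (4.75, others 5.31 to 5.53), in lipid uptake (8.69, 8.80 to 8.84) and in coagulation (8.75, 8.79 to 8.81), and high in Gm13609 (8.90, 7.87 to 8.16).

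ApoE-KO replicate 1 was high in Abca1 (8.37, others 7.73 to 7.89) and Btnl9 (7.57, 7.07 to 7.20). ApoE-KO replicate 3 was high in Ccn2 (7.96, 7.40 to 7.52) and Reln (3.52, 3.39 to 3.42), replicate 2 low in Rsad2 (5.92, 6.23 to 6.34) and replicate 4 low in the heat shock list (7.31, 7.44 to 7.46). Among ApoE-Stab2-KO arrays, replicate 3 was high in Apoe (5.41, 4.93 to 5.08), replicate 2 in Lss (7.66, 7.37 to 7.47) and replicate 4 in Cd36 (10.59, 10.44 to 10.50), while replicate 5 was low in Pfkfb3 (6.30, 6.44 to 6.48) and replicate 4 in fibroblast markers (4.85, 4.94 to 4.98). ApoE-Stab1-KO replicate 1 was high in Cyp26b1 (8.24, 7.90 to 8.03), replicate 2 in blood cell markers (4.0, 3.97 to 3.98), and replicate 4 was low in scavenger receptors (7.21, 7.27 to 7.30). Wildtype replicate 2 was high in Fbp1 (6.83, 6.50 to 6.60) and replicate 3 in immediate early genes (7.86, 7.75 to 7.78).

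Among the 723 probe sets with no gene symbol, which the comparisons did not use, 8 passed the threshold for ApoE-KO minus wildtype plasma, 10 for ApoE-Stab1-KO minus wildtype and 4 for ApoE-Stab2-KO minus wildtype.

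ApoE-Stab1-KO replicate 1 stood apart over all genes. The SD of its deviations from the group mean was 0.208, against 0.128 to 0.156 for the other 5 arrays of its group, and limma gave it an array weight of 0.377. Noise of dim probe sets only is argued against, since over genes above the median level its deviation SD was 0.249, more than the 0.171 of the next array by over the SD of the other arrays (0.0188). Cells of another type in the well could not be excluded: the largest excess of a marker list over the highest of the other 5 arrays was 0.0311, for muscle cell markers, within the bound set for it. No biological explanation was tested, because the labels do not distinguish this array from the others of its group.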

How the results depend on the processing

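Protein-coding genes only and the exact permutation of list means were chosen after seeing the data, and the other settings were planned. No result reversed. For 128 calls of named genes under 2613 combinations with an alternative, 2196 calls held and 417 were lost. The cholesterol synthesis list was called under each alternative in the 3 comparisons with wildtype plasma; against ApoE-KO plasma both double knockouts lost it only under the permutation test (adjusted p = 0.0649). Normalizing or centring again moved no count beyond 1.5 times, which tests little since the arrays already shared nearly 1 distribution.

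Counts of genes moved as follows, and the cause was not tested except where fewer genes or arrays enter by construction. For ApoE-Stab1-KO minus ApoE-KO (1 with all choices as planned), trend and robust settings gave 2, the 2 groups alone 0 and the fold minimum 0. For ApoE-Stab2-KO minus ApoE-KO (6), genes above the median level gave 2, array weights 18, the 2 groups alone 1 and the fold minimum 1. For ApoE-Stab2-KO minus ApoE-Stab1-KO (12), trend and robust settings gave 21, protein-coding genes 2, the 2 groups alone 4 and the fold minimum 6. For ApoE-KO minus wildtype (131), array weights gave 212, the 2 groups alone 80 and the fold minimum 12. For ApoE-Stab1-KO minus wildtype (90), genes above the median level gave 151, the 2 groups alone 21 and the fold minimum 11, and for ApoE-Stab2-KO minus wildtype (44) the fold minimum gave 4. Leaving out 1 array at a time gave 0 to 2, 0 to 12, 8 to 37, 55 to 109, 54 to 124 and 20 to 41 in these 6 comparisons, and 87 to 197 for the F-test (135).

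Of lists called for ApoE-Stab1-KO minus ApoE-KO (9), 1 was called with an estimated correlation, 2 with fry, 0 with the permutation and 5 to 9 with 1 array left out. For ApoE-Stab2-KO minus ApoE-KO (4) these were 1, 1, 0 and 2 to 5. For ApoE-Stab2-KO minus ApoE-Stab1-KO (1) they were 0, 0, 0 and 0 to 1, and 0 with genes above the median level. ApoE-KO minus wildtype (7) had 4 with an estimated correlation and 12 with the permutation, and ApoE-Stab1-KO minus wildtype (8) had 4 with an estimated correlation. The scavenger receptor list of ApoE-Stab1-KO minus wildtype was lost among genes above the median level (adjusted p = 0.135). With the ApoE-KO arrays split, the correlations between comparisons were -0.0177, -0.029 and -0.1585 in place of 0.3829, -0.4249 and -0.5661, because the compared differences then share no array.

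With the replicate number as a block, 0 genes passed for ApoE-Stab1-KO minus ApoE-KO, 0 for ApoE-Stab2-KO minus ApoE-KO and 88 in the F-test, and the other counts stayed within 1.5 times. No clear pairing of the arrays by number was seen. Of 33 same-numbered pairs, 1 had deviations correlated above 0.1 (range -0.0958 to 0.1065, median 0.0121), and 6 of 23 arrays matched their own number best. The number of matches to be had by chance was not computed, so a weak pairing is not excluded. Signal over background limits dim genes such as Postn, Reln, Aqp4 and Olfr372, which lay below the median level of the arrays.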

Other observations

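Of the tests in this part, the comparison of the cholesterol synthesis list with matched random lists was chosen only after the result was seen, as were the set of genes shared by the 3 knockout plasmas, the tests of its overlap and Fisher's exact test. The others were written before their own results. Those on the cholesterol synthesis list and on calls outside protein-coding genes nevertheless address patterns already seen in these data.

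In all 3 comparisons with wildtype plasma, 22 genes passed in the same direction, 14 of them higher and 8 lower with each knockout plasma. Besides Lss, Msmo1, Cyp51 and Cd36, the higher genes included Sprr1a (log2 difference 1.16 with ApoE-KO, 0.96 with ApoE-Stab1-KO and 1.09 with ApoE-Stab2-KO plasma), the semaphorins Sema3c (0.74, 0.50 and 0.62) and Sema3e (0.50, 0.49 and 0.48), and Vegfa (0.26, 0.25 and 0.35). Cyp26b1, which degrades retinoic acid, was higher (0.47, 0.51 and 0.73), as were Dhrs9, a retinol dehydrogenase gene (0.33, 0.37 and 0.26), Cyp1b1 (0.45, 0.39 and 0.46) and the EGF receptor ligand gene Ereg (0.30, 0.29 and 0.29). The lower genes included Dll4 (-0.46, -0.56 and -0.40), Pdgfb (-0.28, -0.33 and -0.31), Smad1, a mediator of BMP signalling (-0.25, -0.26 and -0.25), the endothelial adhesion gene Mcam (-0.27, -0.26 and -0.31), the homeobox gene Hlx (-0.33, -0.31 and -0.42), Fbp1 (-0.41, -0.37 and -0.34) and Nwd1 (-0.57, -0.40 and -0.48). Of the genes named here, Sprr1a, Sema3c, Sema3e, Msmo1, Cyp51, Pdgfb and Mcam passed in all 3 comparisons whichever array of the groups compared was left out. Each of the other 12 lost its call in at least 1 comparison. With only the 2 groups fitted, Sema3c (adjusted p = 0.0537) and Cyp51 (0.0883) lost their limma calls for ApoE-Stab1-KO minus wildtype plasma.

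The calls against wildtype plasma shared 24 higher and 17 lower genes between ApoE-KO and ApoE-Stab1-KO plasma, where independent lists of these sizes would share 0.146 and 0.0894. ApoE-KO and ApoE-Stab2-KO plasma shared 19 and 13 (0.0952 and 0.0304), and ApoE-Stab1-KO and ApoE-Stab2-KO plasma 15 and 9 (0.0487 and 0.0304), with 0 genes called in opposite directions. These comparisons use the same wildtype arrays. In 100 draws of simulated unchanged groups the overlap was at most 1, 0 and 0. Groups without differences leave few genes to call, so these draws cannot tell how much the shared arrays add to the overlap. With the wildtype arrays split 3 and 3 in 20 ways, the median overlap was 0 (range 0 to 0), 2 (0 to 3) and 0 (0 to 0), at median calls of 8 for ApoE-KO, 0 for ApoE-Stab1-KO and 6 for ApoE-Stab2-KO plasma, so the split leaves too few calls to tell the share of the common arrays.

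Other splits of the same arrays were fitted, 100 per comparison with the real one included. As many genes as the real split gave were called in 3 splits for ApoE-Stab1-KO minus ApoE-KO (real 1, highest other 12), in 1 for ApoE-Stab2-KO minus ApoE-KO (real 6, highest other 1) and in 2 for ApoE-Stab2-KO minus ApoE-Stab1-KO (real 12, highest other 18). For each comparison with wildtype plasma it was 1, with ApoE-KO (real 131, highest other 15), ApoE-Stab1-KO (real 90, highest other 2) and ApoE-Stab2-KO plasma (real 44, highest other 1), and for the F-test 1 (real 135, highest other 1). The share of splits with as many calls was under 0.05 for each of the 7 results, without adjustment over them. Other splits called more genes than the real one for ApoE-Stab1-KO minus ApoE-KO and for ApoE-Stab2-KO minus ApoE-Stab1-KO. A random grouping is therefore not excluded for these comparisons. For the other results no other drawn split called as many genes as the real one, which argues against a random grouping. The split of ApoE-Stab1-KO and ApoE-KO arrays that called 12 genes, several times the real count, may point to a structure of those arrays other than the plasma groups, which was not tested.

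The mean of the cholesterol synthesis list was highest with ApoE-KO plasma, lowest with wildtype plasma and between them with both double knockout plasmas, though not every member followed this order (Idi1 was highest with ApoE-Stab2-KO plasma). An array shift that depends on signal intensity is argued against: 0 percent of 10000 random lists matched on mean expression had a median as large in any of the 3 comparisons (random medians -0.118 to 0.111, -0.0985 to 0.0756 and -0.0887 to 0.0885). The growth state of the cells was not settled: with the cell cycle list mean as a covariate the difference between ApoE-KO and wildtype plasma was 0.3918 ± 0.0328 (SE), against 0.3904 ± 0.0301 without it, but the covariate had no slope beyond its spread (0.0291 ± 0.2248), so the adjustment moved nothing and decides nothing. A candidate explanation, a lower sterol supply to the cells, may raise these genes and lower LXR targets, but within groups the list mean did not correlate with the mean of 6 LXR target genes over 23 arrays (r = -0.0033, permutation p = 0.988; rho = 0.0109, p = 0.963; r = -0.109 without the 2 arrays farthest from the median; 1 relation, so adjusted values are the same). That test left the hypothesis open. For the comparisons with wildtype plasma alone, a difference in diet between donors stays open and untested; the labels give the 3 knockout donor groups the same diet.

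Calls outside protein-coding genes appeared in each comparison of ApoE-KO or ApoE-Stab1-KO with ApoE-Stab2-KO or wildtype plasma (2 of 6, 9 of 12, 13 of 131 and 18 of 90 calls), and in neither other comparison, where limma called 0 of such genes among 1 and 44 called in all, with 1377 and 2097 genes at an unadjusted p under 0.05. By Fisher's exact test, which treats genes as independent, only 9 of 12 was above the share of such genes among all tested. The shares of 13 of 131 and 0 of 44 were below it. If arrays had been handled in 2 sets of 2 groups, genes of this class should differ most for this pairing, and 656 of 5021 (13.1%; 32 of the 5021 have no reference entry) had an unadjusted p under 0.05 for it, against 341 (6.79%) and 300 (5.97%) for the other pairings. The pairing was taken from calls of these same genes, so this count largely restates them and gives little support for handling sets. The shares of protein-coding genes were 13.5%, 8.28% and 5.82%. The larger difference for this pairing was therefore not particular to genes outside the protein-coding class. After adjustment 53 of the 5021 and 103 of 19683 protein-coding genes passed for this pairing, and 2 and 21 for the next. A handling set, which no label gives, could not be separated from the plasma groups it would follow. A single array, ApoE-Stab1-KO replicate 1, is argued against as the source of these calls, since ApoE-Stab2-KO minus ApoE-Stab1-KO had 14 such calls without it and 9 with it. Their share of all calls did depend on it (14 of 37 without it and 9 of 12 with it), and ApoE-Stab2-KO minus wildtype had 1 without it. Recovery of small RNA stays open, with 66.0% of 106 snoRNA genes (70) lower in ApoE-KO and ApoE-Stab1-KO arrays, between the bounds set for and against it.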
